A study of Mus musculus with 8 samples.

How the data were processed

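RNA from whole colons of 4 wildtype and 4 Ihh knockout mice had been extracted, amplified with the Illumina TotalPrep method and labelled with Cy3, per the labels. The array identifiers in the labels place all 8 samples on 1 Illumina beadchip. The deposited table of raw values gives, per the file headers, an average signal intensity and a detection p-value for each of 25697 probes on each array. GenomeStudio is named in the submitters' processing notes, with a version not given in the sources used here. The intensity values are on a linear scale with minima of 102.6 to 120.0 over the arrays, so they were treated as not background subtracted, a step that no header or label records. The detection p-value columns deposited by the authors compare each probe with the array's negative controls, as is usual for this platform. A second deposited table, the authors' processed intensity values, has the same minimum (109.6) and maximum (60183.4) on all arrays and medians of 215.35 to 215.467. A quantile normalization of the raw intensity values on the linear scale matches it to within 0.0278 on the log2 scale, so it was used on a log2 scale as an alternative. Its values are neither logged nor centred, and the step that made it is not stated. All columns of both tables could be tied to a sample through its labels. No genome build applies to the values.

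Probes were named from the platform annotation that came with the value table. Of all probes, 23978 had 1 gene symbol, 0 had several and 1719 had none. Through the Entrez ID, 23962 matched a gene table of assembly GRCm38.p6, which changed 0 symbols. Of the probes tested, 855 were unnamed and entered the adjustment for multiple testing only. For a gene with several tested probes the probe with the highest mean log2 value was used. Of 134 genes that the rule below names, 27 had several tested probes, and in 4 (Acadl, Egfl7, Hoxa13 and Insig1) the probes differed in sign.

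Values were background corrected with normexp from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were tested, without regard to group. A linear model with genotype as its only term was fitted with lmFit and eBayes, with all 8 arrays, and p-values were adjusted over all probes tested by the method of Benjamini and Hochberg. Tests were two-sided and calls were made at an adjusted p under 0.05. A probe detected on no array of a group has only a bound there. Its fold is given as "at least", and compares the mean log2 value of the other group with the mean of, per array, the higher of the lowest detected signal and the probe's own value.

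Before the data were examined, 32 gene lists covering pathways, the cell types of the colon and attached tissue were fixed, and the tests, the alternatives and the rule for named genes were written down. Each list with at least 4 measured members was tested with camera with a preset correlation of 0.01, and beside it with camera with an estimated correlation and with fry. Adjustment was over the 32 lists. The score of a list in a mouse is the mean of its genes' log2 values after each gene's mean over the 8 arrays is subtracted, and genotypes were compared by an exact permutation test of the 70 assignments. The named genes are Ihh and the measured hedgehog targets, the up to 15 genes per direction with the largest change among those past the threshold whose groups do not overlap (or, where none passes, the 5 with the smallest p), and the up to 4 members of each list with the smallest p. The text names some of the last group. The skeletal muscle and skin marker lists, and the fits with sex, with these scores or with only 4 mice, were added after the data had been seen.

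Pairwise correlations between arrays were 0.943 to 0.985 over the probes tested. The groups lay at separate positions of the same beadchip, A to D and E to H, so position was tried as a term. The alternatives were no background correction, median scaling, cyclic loess, the authors' table, no filter on dim probes or a filter of detection p under 0.01 on all arrays, the replicate number as a block, array position, array weights, a trended and robust variance prior, the mean of a gene's probes, a fold change of at least 1.5, and leaving out each mouse in turn.

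The fit was tested on simulated data for the comparison of knockout with wildtype, with 10 simulations of 14754 probes of which 200 were changed. It recovered 14.6% of the probes changed by 0.5 on the log2 scale, 62.4% of those changed by 1, 90.6% of those changed by 2 and 98.4% of those changed by 3, and 4.84% of its calls were false. A list shifted by 0.5 was called in 10 of 10 simulations, and 2 of 310 tests of other lists were called. The simulated probes varied independently of each other. In the data the estimated correlation between genes was 0.52 for the interferon and 0.65 for the proliferation list. The simulation therefore does not give the rate of false list calls in these data. The simulations also held many large changes, with 1405 calls over 10 runs, against 2 genes called in the data. With more calls the adjusted threshold is easier to pass, so the recovered shares do not hold for these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.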

Results

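Gene expression was measured in whole colons of 8 C57BL/6 mice on 1 Illumina beadchip, with 4 colons per genotype. Knockout mice carried Ihh alleles flanked by recombination sites together with Villin-CreERT2, a recombinase made in the intestinal epithelium and switched on by tamoxifen. Wildtype mice carried the recombinase and intact Ihh. Both genotypes were given 1 mg tamoxifen on each of 5 days, and colons were taken at day 7. Ihh encodes Indian hedgehog, a ligand that the intestinal epithelium releases and that cells of the underlying mesenchyme receive. The comparison asks what changes in the colon when Ihh is targeted for deletion in the epithelium. The arrays do not show how complete the deletion was. The titles number 4 colons per genotype, which were taken as 4 mice. Mean probe intensity lay between 902 and 1258 per array, and 14465 to 15040 of the 25697 probes were detected. The tests covered 14754 probes, which gave 10184 named genes.

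The samples differed in ways that the genotype labels do not give. Xist and Y-linked probes showed a male pattern in 1 of 4 wildtype and 3 of 4 knockout mice. Knockout 4 stood apart from the other arrays, with a mean correlation of 0.956 with them and a first principal component score of 58.1 on an axis holding 29.8% of the variance. Transcripts of skeletal muscle were far higher in wildtype 2, wildtype 3, knockout 2 and knockout 4 than in the other mice. Myh8, a myosin heavy chain of developing and specialised striated muscle, had log2 intensities of 11.2 to 12.7 in these 4 colons and 5.50 to 5.71 in the others. Transcripts of skin and stratified epithelium also varied, with Krt14, a keratin of basal skin cells, between 6.63 in wildtype 1 and 15.2 in wildtype 4. These markers were listed after the values had been seen. By an exact permutation test of the score per mouse, neither marker group passed, with p = 0.857 for skeletal muscle (difference 0.24) and p = 0.543 for skin (difference -0.66). Of 21 skeletal muscle genes 13 were higher in the knockout, with a median of 0.30, and of 24 skin genes 23 were lower, with a median of -0.67.

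Ihh itself and the genes that hedgehog signalling switches on were lower in the knockout colons. Ihh had a log2 intensity of 10.4 ± 0.153 in wildtype and 9.34 ± 0.245 in knockout mice (SD, n = 4 each), and every knockout colon lay below every wildtype colon. The difference of -1.05 (SE 0.149) is a 2.07-fold lower signal. Its limma p of 6.16e-05 became 0.130 after adjustment over all probes, so Ihh did not pass the threshold of 0.05. The probe was detected on all 8 arrays, and its place relative to the deleted part of the gene is not given in the sources used here. Hhip, which encodes a decoy receptor for hedgehog ligands and is itself a hedgehog target, fell by at least 1.80-fold. It was detected in all 4 wildtype and in 0 of 4 knockout colons, and its fitted log2 change was -1.24 (SE 0.114, adjusted p = 0.0131). Without background correction the Hhip change was -0.36 and not called (adjusted p = 0.205), so the bound holds for background corrected values. Foxf1, a forkhead factor of the gut mesenchyme, differed by -0.53 (SE 0.102), Nkx2-3, a homeobox gene of the same tissue, by -0.64 (SE 0.142), and Foxf2 by -0.44 (SE 0.174). Adjusted over the list alone, these 3 and Hhip passed, against 1 of 5 over all probes tested. Bmp4 differed by -0.12 (SE 0.118, adjusted p = 0.706). The other targets on the array could not be tested, since Gli1 and Foxl1 were detected in 0 colons and Ptch1 in 1.

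**Figure D1:**
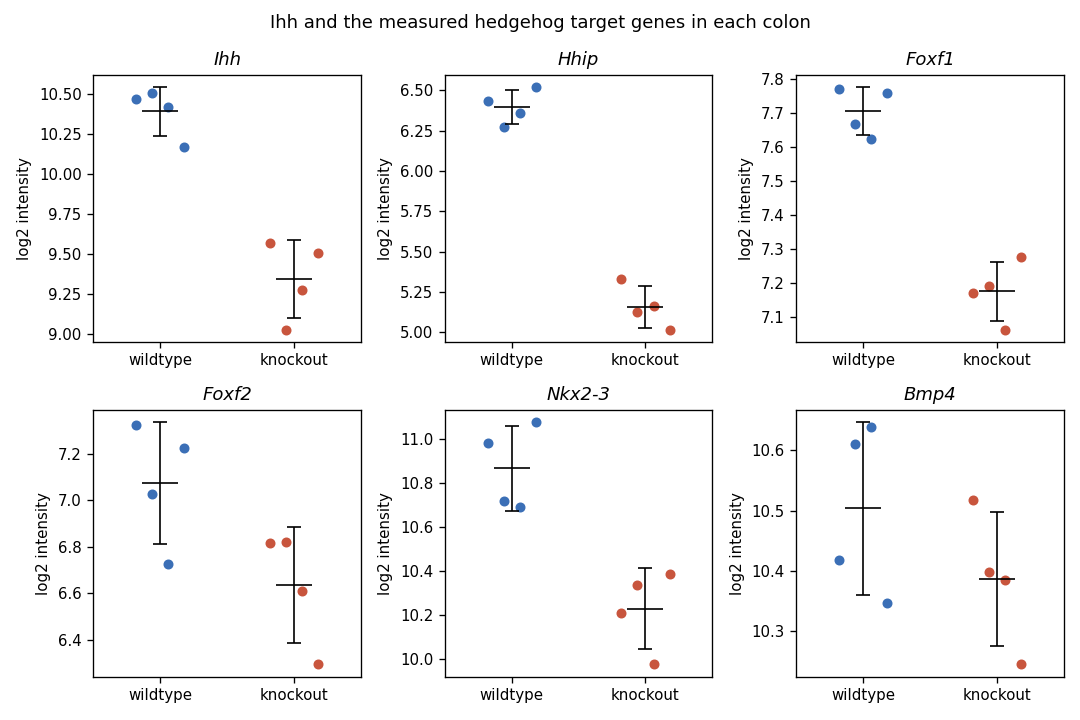
Log2 intensity of Ihh and of the 5 measured hedgehog target genes in each colon, by genotype. Points are single colons, and the bar and whiskers are the mean and SD of 4 colons. Hhip lies at 5.02 to 5.33 in the knockout colons, below its range of 6.27 to 6.52 in wildtype, while the Bmp4 values of both genotypes overlap. The vertical axes do not start at 0.

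As a list, the 5 measured hedgehog targets were all lower in the knockout, with a median log2 change of -0.53. The camera test with a preset correlation gave an adjusted p of 3.10e-06 over 32 lists, and adjusted p = 0.124 with an estimated correlation. The rotation test fry, which asks whether the genes of a list move 1 way on balance, also called the list (adjusted p = 0.000809). Without background correction the median was -0.27. The hedgehog pathway components, 6 measured genes that send, relay or regulate the signal, had a median of -0.29 and were not called (adjusted p = 0.161). Gpc3, a regulator in this list, was at -0.61.

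Across all genes, limma called 2 genes at adjusted p under 0.05, and both were lower in the knockout. Besides Hhip, this was Dnaic1, which encodes an intermediate chain of the dynein motor of cilia. Its log2 change was -1.69 (SE 0.156, adjusted p = 0.0131), and it was detected in 4 wildtype and 2 knockout colons. Actc1, which encodes cardiac alpha actin, came next among the lower genes (log2 change -1.20, adjusted p = 0.0939, at least 1.69-fold). Actc1 passed in the limma fits with array weights (adjusted p = 0.0402) and with the mean of a gene's probes (adjusted p = 0.0457). It lies outside the rule for named genes and was chosen after its values were seen. No gene was called higher by limma, while 682 genes were higher and 442 lower at an unadjusted p under 0.05, against 509.2 expected by chance in both directions together. In 782 genes the 4 values of 1 genotype lay wholly above those of the other, 494 of them higher in the knockout. This is 7.68% of the genes, where chance gives 2.86% on average over all regroupings of the mice. Genes vary together, so single regroupings can lie far from that average, and their shares were not computed. The call of Hhip was lost without 7 of the 8 mice in turn (log2 changes of -1.28 to -1.19) and that of Dnaic1 without 6 (-1.73 to -1.65). Both were lost with sex as a term (-1.19 and -1.79, adjusted p = 0.179 and 0.131), and Dnaic1 without background correction (-0.59, adjusted p = 0.0890). Without knockout 1, 10 genes passed, of which 8 were higher. Knockout 1 was the only knockout with a female pattern, so leaving it out made the sexes more uneven between the genotypes.

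The 5 genes with the smallest p among the higher ones did not pass the threshold. Nlrc5, a transactivator of MHC class I genes, differed by 1.61 (SE 0.214, adjusted p = 0.130), and Tap1, which carries peptides for MHC class I loading, by 1.09 (adjusted p = 0.191). Oas2, an interferon-induced antiviral enzyme, differed by 2.29 (SE 0.394, adjusted p = 0.191). Cxcl9, a chemokine induced by interferon gamma, differed by 1.49 (adjusted p = 0.191). Bod1l was detected in 0 of 4 wildtype and 4 of 4 knockout colons, at least 1.28-fold higher (adjusted p = 0.131). Without knockout 1, the setting with the more uneven sexes, Nlrc5 and Oas2 passed (limma adjusted p = 0.0498 and 0.0133).

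Of the 32 gene lists, camera with the preset correlation called 18, of which 10 were higher and 8 lower in the knockout. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.124. By fry, 3 passed (hedgehog targets, BMP pathway and interferon response). An exact permutation test of the score per mouse cannot go below p = 0.0286 with 4 mice against 4, and 7 lists reached that value. Adjusted over the 32 lists, the smallest exact p was 0.131, so 0 lists passed that test. With the sex of the mice as a term 14 lists were called, with the skeletal muscle and skin scores as terms 16, and in the 4 mice with low skeletal muscle markers 11. Array positions A to D held the wildtype and E to H the knockout samples, and with position as a term 7 lists were called, not all of them among the 18.

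**Figure D2:**
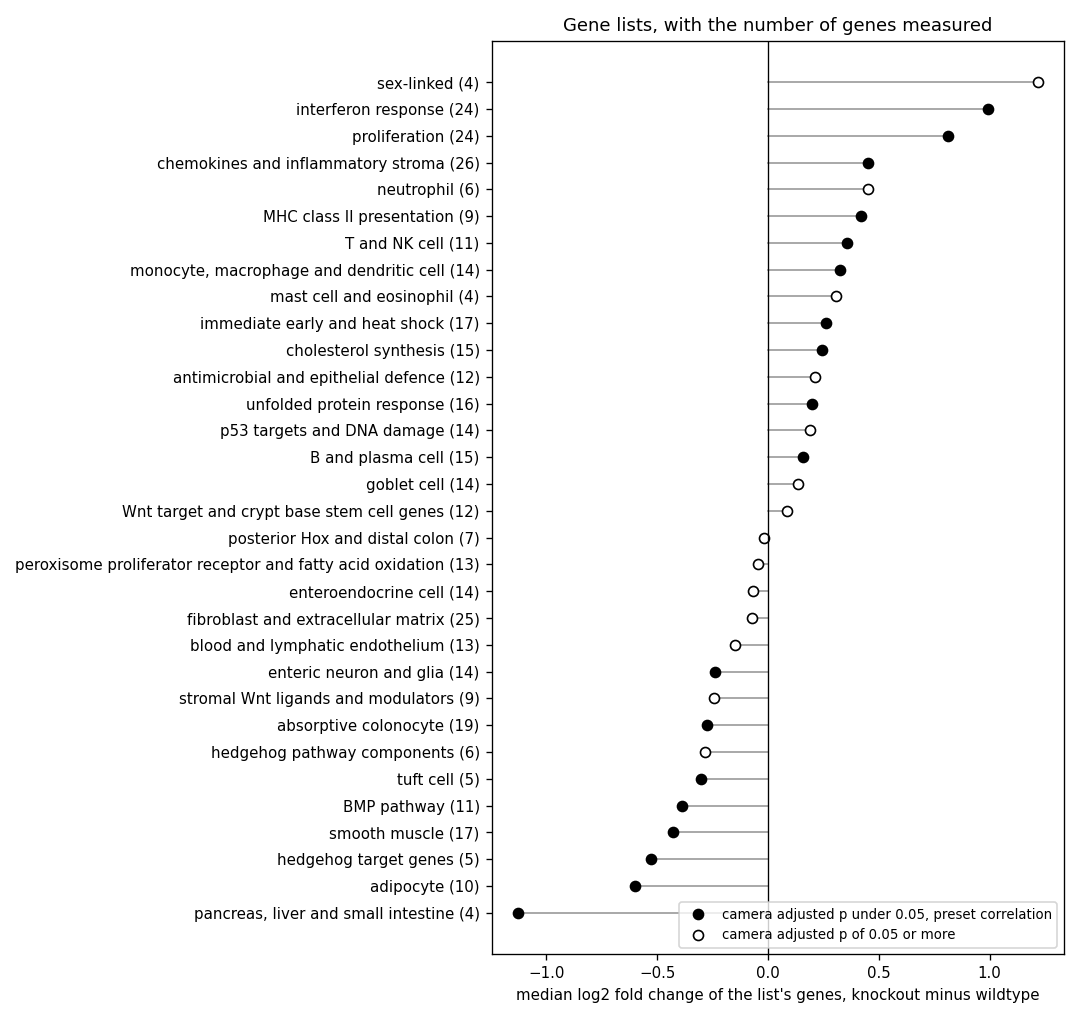
Median log2 fold change, knockout minus wildtype, of the measured genes of each list, with their number in brackets. Filled points are the 18 lists called by camera with a preset correlation, from the interferon response at 0.99 to the pancreas, liver and small intestine markers at -1.13, and 0 of them passed with an estimated correlation.

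Genes of the interferon response were higher in the knockout colons. All 24 measured members were higher, with a median log2 change of 0.99, or 1.99-fold. Adjusted over the list alone 21 passed, and 0 passed over all probes. Usp18, which limits interferon signalling, differed by 2.06 (SE 0.368), Tap1 by 1.09 and Gbp3, an interferon-induced GTPase, by 0.85 (SE 0.157). The list had a camera adjusted p of 4.18e-23, and adjusted p = 0.197 with an estimated correlation. The score was above that of each wildtype mouse in each knockout mouse (exact permutation p = 0.0286, the smallest possible). It ranged from 0.0367 in knockout 1 to 0.947 in knockout 2, and knockout 1 was also the 1 female-pattern knockout mouse. Without background correction the median was 0.66.

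MHC class II presentation moved the same way, with 9 of 9 genes higher and a median of 0.42 (camera adjusted p = 2.11e-05, adjusted p = 0.302 with an estimated correlation). H2-DMa (0.65), Cd74, the invariant chain (0.53), H2-DMb1 (0.54) and H2-Ab1 (0.45) passed when adjusted over the list alone. With array position as a term the list was not called (0.28, adjusted p = 0.177), and without wildtype 2 its median was 0.27 and the call held. Of 26 chemokines and inflammatory stromal genes, 17 were higher, with a median of 0.45 (camera adjusted p = 0.00159, adjusted p = 0.302 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell. Those that rose were Cxcl9 (1.49), Cxcl10 (1.02), both induced by interferon, and Ccl28 (1.01), Ccl7 (1.02) and Ccl4 (1.03), which draw leukocytes. Tslp, an epithelial cytokine, fell by at least 1.21-fold. Ccl4 and Tslp lie outside the rule and were chosen after their values were seen. Without knockout 4 the chemokine median was 0.18, and in the 4 mice with low skeletal muscle markers it was not called (0.14, adjusted p = 0.0789). With array position as a term it turned to -0.28 (adjusted p = 0.112).

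T and NK cell markers had a median of 0.36, with 11 of 11 higher, among them Nkg7 (0.62) and Cd2 (0.52), and 0 passed when adjusted over the list alone (camera adjusted p = 0.00188, adjusted p = 0.328 with an estimated correlation). That call was lost with the strict detection filter (0.20, adjusted p = 0.176) and in the 4 mice with low skeletal muscle markers (0.28, adjusted p = 0.548). Without background correction the T and NK cell median was 0.16 and the call held. Monocyte, macrophage and dendritic cell markers had a median of 0.32, with 12 of 14 higher (camera adjusted p = 0.00669, adjusted p = 0.443 with an estimated correlation). Fcgr1, an Fc receptor, rose in that list alone (0.65), and the list was not called without knockout 4 (0.20, adjusted p = 0.0851) or in the 4 mice with low skeletal muscle markers (0.037, adjusted p = 0.804). B and plasma cell markers had a median of 0.16 with Cd79a, a part of the B cell receptor, at 0.74 (camera adjusted p = 0.0395, adjusted p = 0.511 with an estimated correlation). That call was lost without 6 of the 8 mice in turn, with medians of 0.13, 0.014 and 0.13 without wildtype 1, 2 and 3 and of 0.12, 0.094 and 0.21 without knockout 1, 2 and 3. It was also lost without background correction (0.055), in the authors' table (0.060) and with the mean of a gene's probes (0.079). The same held with no filter on dim probes (0.13) and with the strict detection filter (0.098). With array position as a term, the T and NK cell median turned to -0.12, that of monocytes and macrophages to -0.23 and that of B cells to -0.021, and 0 of these 3 lists were called. Markers of neutrophils (median 0.45, adjusted p = 0.323, called at 0.74 with the skeletal muscle and skin scores as terms and at -1.27 with position), of mast cells and eosinophils (0.30, adjusted p = 0.396) and of antimicrobial and epithelial defence (0.21, adjusted p = 0.332) were not called. Ido1, an interferon-induced enzyme of tryptophan breakdown in the last list, differed by 1.64 (SE 0.532, adjusted p = 0.387).

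Proliferation genes were higher in the knockout colons, with 24 of 24 measured members above wildtype and a median log2 change of 0.81, or 1.76-fold. Adjusted over the list alone 19 passed, among them Ccne1, the cyclin that drives entry into DNA synthesis (0.96, SE 0.183), and Mcm5 and Mcm2, parts of the replicative helicase (0.83 and 0.82). The list had a camera adjusted p of 1.92e-17, and adjusted p = 0.302 with an estimated correlation. The score was higher in each knockout than in each wildtype mouse (exact permutation p = 0.0286). Knockout 4, which stood apart in all genes, had the highest score at 0.850. Without it the list median was 0.62 and the call held. With array position as a term the median was 0.42, and without background correction 0.53.

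**Figure D3:**
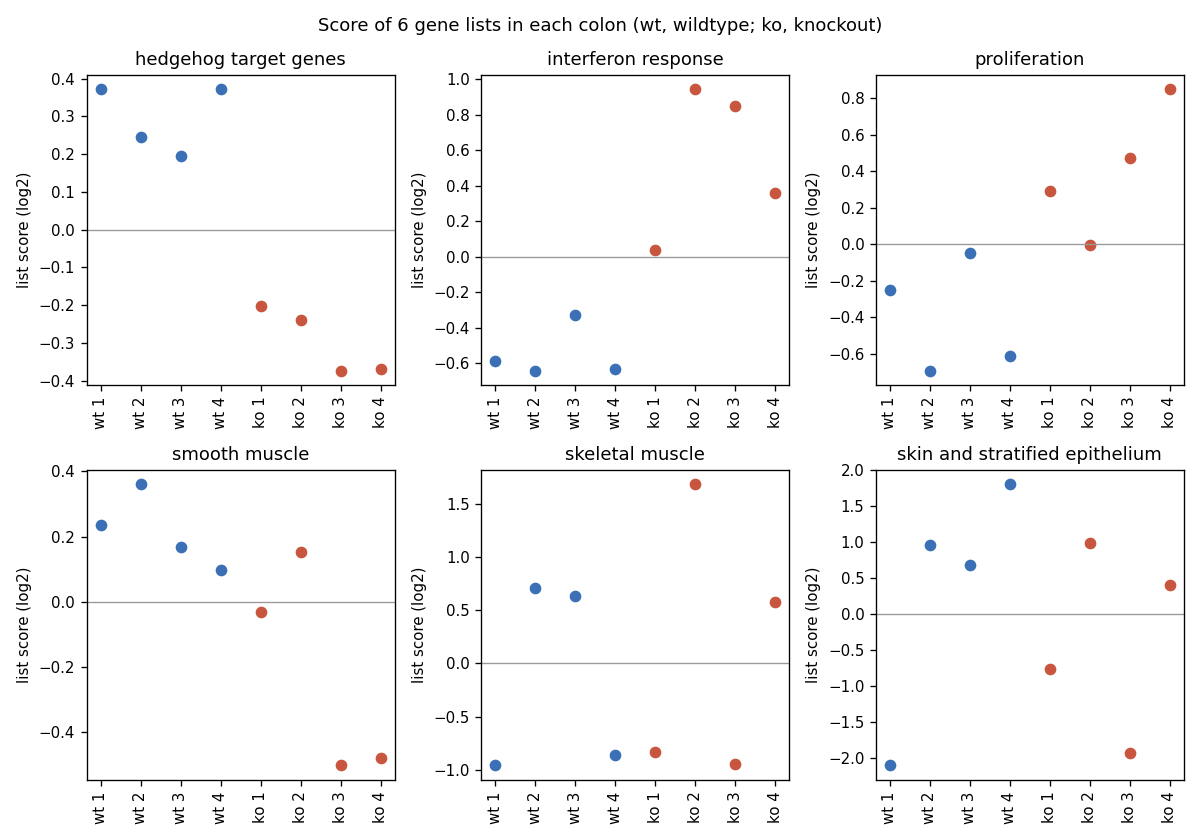
Score of 6 gene lists in each colon, which is the mean over the list of each gene's log2 intensity minus its mean over the 8 colons. Hedgehog targets, interferon response and proliferation separate the genotypes, smooth muscle overlaps, and skeletal muscle is above 0.57 in 4 colons of both genotypes and below -0.83 in the others. The skeletal muscle and skin lists were written after the values had been seen.

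Markers of the epithelial cell types moved less than the proliferation genes. Absorptive colonocyte markers had a median of -0.28, with 16 of 19 lower, for example Scnn1g (-0.58) and Ceacam20 (-0.40), neither past the threshold (camera adjusted p = 0.0122, adjusted p = 0.441 with an estimated correlation). Knockout 4 had the lowest colonocyte score, -0.69, and without it the median was -0.092 and the call was lost (adjusted p = 0.259). With array position as a term the colonocyte median turned to 0.33 (adjusted p = 0.177) and that of tuft cells to 0.071 (adjusted p = 0.960). Tuft cell markers had a median of -0.30 over 5 genes, with Trpm5, a cation channel of taste and tuft cells, at -0.73 (camera adjusted p = 0.0232, adjusted p = 0.302 with an estimated correlation). That call was lost with sex as a term (-0.22, adjusted p = 0.0744) and without wildtype 2 (-0.30, adjusted p = 0.0502). In the 4 mice with low skeletal muscle markers, neither the colonocyte list (-0.030, adjusted p = 0.658) nor the tuft cell list (-0.23, adjusted p = 0.0789) was called by camera. Goblet cell (median 0.14, adjusted p = 0.463) and enteroendocrine cell markers (-0.069, adjusted p = 0.396) were not called. Wnt target and crypt base stem cell genes had a median of 0.084 and were not called (adjusted p = 0.660), with Lgr5, a stem cell receptor, at -0.75 and Cd44, a Wnt target, at 0.30, neither past the threshold.

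Smooth muscle genes were lower in the knockout colons. The median log2 change was -0.43 over 17 genes, of which 16 were lower. Cald1, an actin-binding regulator of contraction (-0.87), Myocd, the coactivator of the smooth muscle program (-0.94), and Lmod1, an actin nucleator (-0.51), had the smallest p values but did not pass, and 0 genes passed when adjusted over the list alone. The camera adjusted p was 5.53e-06, and adjusted p = 0.302 with an estimated correlation. The scores of both genotypes overlapped (exact permutation p = 0.0571). The median was -0.28 without knockout 4, and with array position as a term it turned to 0.15 (adjusted p = 0.673).

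Genes of the BMP pathway, which lies downstream of hedgehog in the gut mesenchyme, were lower too. The median was -0.39, with 10 of 11 lower, among them the ligand Bmp5 (-0.55) and the BMP targets Id1 (-0.27) and Id3 (-0.39), and 0 passed when adjusted over the list alone. The BMP antagonists Grem1 (-0.61), Fst (-0.43) and Chrd (-0.31) were lower as well, so the list does not show which way BMP signalling moved. The ligand Bmp4, counted among the hedgehog targets instead, differed by -0.12. Camera gave an adjusted p of 0.00348, and adjusted p = 0.197 with an estimated correlation. Without knockout 4 the median was -0.22, and with array position as a term it was -0.13 and not called (adjusted p = 0.485). Stromal Wnt ligands and modulators had a median of -0.24 and were not called (adjusted p = 0.0664), with Dkk3 at -0.45 and Wnt5a at -0.32. Fibroblast and extracellular matrix genes (-0.075, adjusted p = 0.280), with Mfap5 at -0.51, and endothelial genes (-0.15, adjusted p = 0.0772) were not called either. Of 25 other settings, the endothelial list was called lower in 10 (-0.12, adjusted p = 0.0452 without background correction, -0.23 without wildtype 1, -0.25 without knockout 2 and -0.20 without knockout 4). The fibroblast list was called lower in 4 (-0.10, adjusted p = 0.00259 without knockout 4) and the stromal Wnt list in 4 (-0.17 without wildtype 2 and -0.15 without knockout 4). Enteric neuron and glia markers had a median of -0.24, with 12 of 14 lower, such as Stmn3 (-0.69), Prph (-0.62) and Chat (-0.79), none past the threshold (camera adjusted p = 0.0160, adjusted p = 0.302 with an estimated correlation). That call was lost without wildtype 2 (-0.23, adjusted p = 0.0502) and without knockout 3 (-0.17, adjusted p = 0.104), with array position as a term (-0.070, adjusted p = 0.609) and with the strict detection filter (-0.38, adjusted p = 0.0547). Without background correction the enteric neuron and glia median was -0.10 and the call held.

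Adipocyte genes were lower in the knockout samples, with a median of -0.60 and 10 of 10 below wildtype, including Adipoq, the fat cell hormone adiponectin (-0.89), and Acvr1c, an activin-type receptor (-1.14), and 0 passed when adjusted over the list alone (camera adjusted p = 0.000494, adjusted p = 0.197 with an estimated correlation). The scores overlapped, with 0.146 in knockout 2 and 0.0765 in wildtype 2 (exact permutation p = 0.0571), and the median was -0.32 without background correction and -1.03 in the 4 mice with low skeletal muscle markers. The 4 measured markers of pancreas, liver and small intestine had a median of -1.13 (camera adjusted p = 0.0166, adjusted p = 0.302 with an estimated correlation). Their scores were 1.62 in wildtype 3 and 2.43 in wildtype 4 and below -0.34 in all other mice. Ctrb1, a pancreatic protease precursor, was detected in 2 wildtype and 2 knockout colons, with a log2 difference of -3.38 (SE 1.84), and Cela1, an elastase, differed by -1.16 (adjusted p = 0.450). The call was lost without wildtype 3 (-1.04, adjusted p = 0.0542) and without wildtype 4 (-0.80, adjusted p = 0.0530). It was also lost with array weights (-0.49), with sex (-0.70), the skeletal muscle and skin scores (-0.83) or position (-0.90) as terms, and in the 4 mice with low skeletal muscle markers (-0.64).

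The remaining lists concern stress, metabolism and position along the gut. Unfolded protein response genes had a median of 0.20 with 14 of 16 higher, such as Hyou1 (0.74), Hsp90b1 (0.42) and Creld2 (0.53), which act in folding in the endoplasmic reticulum (camera adjusted p = 0.00155, adjusted p = 0.302 with an estimated correlation). In the 4 mice with low skeletal muscle markers the list was not called (adjusted p = 0.245), and without knockout 4 its median was 0.13. Immediate early and heat shock genes had a median of 0.26, with Egr1 at 0.82 and Atf3 at 0.39 (camera adjusted p = 0.0392, adjusted p = 0.302 with an estimated correlation). Cholesterol synthesis genes had a median of 0.24, with Idi1 at 0.30 (camera adjusted p = 0.0415, adjusted p = 0.543 with an estimated correlation). The first call was lost without wildtype 1 (0.24), wildtype 2 (0.27), wildtype 4 (0.19) and knockout 2 (0.13) in turn, and the second without wildtype 2 (0.23), wildtype 4 (0.086), knockout 1 (0.21) and knockout 4 (0.10). Both were also lost with array weights (0.22 and 0.14) and with sex (0.17 and 0.20), the skeletal muscle and skin scores (0.14 and 0.097) or position (0.23 and 0.26) as terms. The 4 mice ended the call of the first (0.13), and median scaling (0.28) and the replicate block (0.24) that of the second. Genes of the p53 response (0.19, adjusted p = 0.161, called without knockout 1 at 0.24), of fatty acid oxidation (-0.044, adjusted p = 0.745) and the posterior Hox genes (-0.020, adjusted p = 0.660) were not called. The 4 sex-linked genes had a median of 1.22 with an adjusted p of 0.280.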

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

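The splits of the mice and the comparisons of list scores were planned before their results were seen, while the tests with sex and with the skeletal muscle and skin markers or scores were chosen after. Array position as a term was planned as an alternative, and its use to test the interferon and smooth muscle lists was chosen after. In 12 of 184 groups of 4 mice, over named genes and list scores, 1 mouse lay far from the other 3, where chance gives about 9.2. The log2 intensity of Nlrc5 was 5.64 in wildtype 2 against 6.38 to 6.51 in the other wildtype mice, and that of Cd79a 7.16 in wildtype 4 against 6.93 to 6.95. Fcgr1 was 6.20 in knockout 3 against 6.68 to 6.77 in the other knockout mice. Among the scores, the goblet cell score was -0.23 in wildtype 1 against -0.024 to -0.016, the tuft cell score -0.030 in wildtype 3 against 0.27 to 0.31, and the immediate early and heat shock score -0.011 in wildtype 3 against -0.14 to -0.12. The T and NK cell score was 0.51 in knockout 3 against 0.073 to 0.12, and the sex-linked score 0.80 in wildtype 1, the 1 wildtype mouse with a male pattern, against -0.86 to -0.70. Knockout 4 gave 4 of the 12, with Hyou1 at 7.99 against 7.50 to 7.56, Cela1 at 11.4 against 12.7 to 12.8, the absorptive colonocyte score at -0.69 against 0.011 to 0.14 and the pancreas, liver and small intestine score at -1.83 against -0.45 to -0.34.

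Grouping the 8 mice in all 35 possible ways shows which results chance can give. For the 2 genes past the adjusted threshold chance was not excluded, since 3 of the 35 splits gave as many. Besides the real split, these were the split by sex (3 genes) and that by high skeletal muscle markers (33 genes). Both follow a measured difference between the samples, and all remaining splits called 0 genes. The count at an unadjusted p was largest in the real split, 1 of 35 (1124 genes against 1049 in the highest other split). So was the number of lists called (18 against 14), and chance was excluded at 0.05 for each count taken alone. The absolute medians of the hedgehog targets (0.53 against 0.46), interferon response (0.99 against 0.77) and proliferation genes (0.81 against 0.74) were also largest there. These lists and smooth muscle had the smallest camera p of the 32 lists in the real split, so this rank is no independent support. For list scores the smallest exact p adjusted over the 32 lists was 0.131, so chance stays open for these lists. A share of 1 in 35 is the smallest that 35 splits can give, and it is not adjusted over the results tested. The smooth muscle median was also largest in the real split, 1 of 35, but by little (0.43 against 0.41), and the exact permutation test of its score gave p = 0.0571, so chance stays open for that list. The split by sex, a property that the labels do not give, called 3 genes and 9 lists. With sex as a term 0 genes and 14 lists were called for genotype.

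The split that called 33 genes set wildtype 2, wildtype 3, knockout 2 and knockout 4 against the rest, which points to a structure of the samples. All 33 were higher in these 4 mice, led by Myh8, Defb6, Krt79, Myl3 and Tnnc2. A candidate explanation for part of these genes is striated muscle attached to some of the colons. Of 21 measured skeletal muscle markers, 6 were among the 33 genes, and of the other 15, 8 were higher in each of these 4 mice than in each of the rest. Chance separates 1.43% of genes, but that share holds for unrelated genes and a split fixed beforehand. Markers of 1 tissue vary together, and this split was picked for its many called genes. The skin markers point to a further tissue, since wildtype 4 had the highest skin score (1.81) with a low skeletal muscle score (-0.87). Both kinds of tissue meet the colon at the anus, but no label records where the colons were divided, and no biological explanation was tested.

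The interferon response was higher in the knockout colons. More leukocytes with an unchanged interferon state could move both kinds of list alike, a premise that was not tested. The interferon score minus the mean score of the T and NK, B and plasma, and monocyte lists was higher in knockout mice by 0.80 (exact permutation p = 0.0286, the smallest possible). The mean leukocyte score itself differed by 0.30 (exact permutation p = 0.143). The interferon score alone already reached the smallest p, and the difference was -0.023 in knockout 1 against -0.14 in wildtype 3. The interferon list thus moved further than these leukocyte lists, which does not exclude more leukocytes as a part of the source. Uneven sex was not the whole source, since the median was 0.92 with sex as a term and still called, nor was attached muscle and skin, with 0.91 with both scores as terms. A linear trend over the array positions did not remove the difference either, with a median of 1.03 that was still called (camera adjusted p = 3.89e-08). A step between positions A to D and E to H runs with the genotypes and cannot be told apart from them. That the loss of epithelial Ihh raises interferon-stimulated genes stays a hypothesis, found and tested on the same mice.

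The smooth muscle genes were lower in the knockout colons. Sex as a term left a median of -0.31 and the skeletal muscle and skin scores -0.43, both still called by camera with the preset correlation. The muscle and skin scores thus did not reduce the median. Other groupings of the mice gave absolute medians of up to 0.41, so the fit with sex cannot decide whether uneven sex was the whole source. A smaller share of the whole wall remains possible, since the smooth muscle score minus the fibroblast and endothelial score differed by -0.34 between genotypes, within what regrouping gives (exact permutation p = 0.143), and the endothelial list was called lower in 10 of 25 other settings. Position on the beadchip and genotype cannot be told apart here, since the median turned to 0.15 (adjusted p = 0.673) with position as a term, which runs in the same order as the genotypes. A loss of smooth muscle expression after loss of Ihh stays a hypothesis.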

How the results depend on the processing

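The fits with sex, with the skeletal muscle and skin scores and with only 4 mice were chosen after the data had been seen. Of the results, Ihh was lower in the knockout in every setting run (-1.12 to -0.86) and past the threshold in none (adjusted p of 0.0552 to 0.985). The hedgehog target, interferon and proliferation lists kept their direction in all settings, and their calls in all but the other set tests. With an estimated correlation 0 lists were called, with adjusted p of 0.124 for hedgehog targets (median -0.53), 0.197 for interferon (0.99), 0.302 for proliferation (0.81) and 0.302 for smooth muscle (-0.43). Directional fry called 3 lists and lost proliferation (0.81, adjusted p = 0.0824) and smooth muscle (-0.43, adjusted p = 0.166), and mixed fry called 4 and lost smooth muscle (adjusted p = 0.151). Other scalings moved the median of all genes by under 0.1.

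The 2 genes called, both lower, became 0 without background correction, in the authors' table, with the strict filter, with array position, with sex, with the skeletal muscle and skin scores, and in the 4 mice with low skeletal muscle markers. They became 1 with the trended prior and 4, all lower, with the mean of a gene's probes. At an unadjusted p, 749 were higher and 486 lower without background correction, 649 and 302 with median scaling, 631 and 497 with cyclic loess, 405 and 299 with sex, 500 and 374 with the muscle and skin scores, and 507 and 411 in the 4 mice. The cause was not tested. Fewer probes, mice or residual degrees of freedom enter some of these fits.

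The labels do not say whether the replicate numbers pair the mice, and the values did not show it. The correlations of deviations were 0.14, 0.21, -0.18 and -0.038, and not every sample correlated best with its own number. So few correlations cannot exclude a pairing. With the replicate number as a block the count of genes moved from 2 to 0 and that of lists from 18 to 17.

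Leaving out each mouse in turn gave 0 to 10 genes, with 0 to 8 higher and 0 to 2 lower, and 14 to 18 lists. The ranges of the medians were -0.56 to -0.49 for hedgehog targets, 0.62 to 0.92 for proliferation, -0.53 to -0.28 for smooth muscle and 0.87 to 1.14 for interferon, and Ihh ranged from -1.12 to -0.94. The fibroblast list ranged from -0.10 to 0.054 (without knockout 3), the p53 list from -0.013 (without knockout 4) to 0.24, and the fatty acid oxidation list from -0.081 to 0.014 (without knockout 4).

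Array position as a term runs in the same order as the genotypes. With it 7 lists were called and the most directions turned, with 189 genes higher and 188 lower at an unadjusted p. Among the 7 were lists that the main fit did not call, namely fibroblast (-0.24), endothelial (-0.38) and neutrophil (-1.27), each with a camera adjusted p of 0.0065. Lists turned to 0.15 for smooth muscle, 0.33 for colonocyte, 0.071 for tuft cell, 0.027 for hedgehog components, 0.10 for fatty acid oxidation, -0.28 for chemokines, -0.12 for T and NK, -0.021 for B and plasma cell, -0.23 for monocyte and macrophage, -1.27 for neutrophil, -0.29 for mast cell, -0.26 for p53 and -0.051 for unfolded protein response. Genes turned to 0.087 for Bmp4, 0.034 for Foxf2, 0.49 for Id3, 0.23 for Lgr5, 0.36 for Myocd, 0.11 for Trpm5, 0.23 for Ceacam20, 0.20 for Acvr1c, -0.11 for Cd2, -0.045 for Cd44 and -0.091 for Ccl4. Array weights turned mast cell to -0.053, antimicrobial to -0.0044 and fatty acid oxidation to 0.0097. With no filter hedgehog components turned to 0.0096, with the strict filter enteroendocrine to 0.032, and with the muscle and skin scores posterior Hox to 0.039. In the 4 mice, 11 lists were called, and enteroendocrine turned to 0.049, B and plasma cell to -0.020, neutrophil to -0.046, mast cell to -0.060, antimicrobial to -0.036, p53 to -0.033, fatty acid oxidation to 0.027 and Bmp4 to 0.068. The cause was not tested. Signal over background limits dim genes such as Gli1, and also the fold of Hhip, which was -0.36 on the log2 scale without background correction.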

Other observations

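The genes that other groupings of the mice bring out describe what else the colons held. The transcripts shared by wildtype 2, wildtype 3, knockout 2 and knockout 4 included those of striated muscle, such as Tnnc2 (log2 intensity 9.60 to 11.1 in these mice and 4.69 to 5.15 in the others), Mb, the oxygen store myoglobin (9.66 to 11.3 and 5.17 to 6.23), and Atp2a1, a calcium pump of fast fibres (9.44 to 11.0 and 4.87 to 5.83). Skin and hair genes such as Krt79, Krt2, Flg2, Krt33a and Krtap1-5 were among the same 33 genes. The skin score was lowest in wildtype 1 (-2.11) and knockout 3 (-1.94). Lor, a protein of the outer skin layer, had a log2 intensity of 6.27 and 6.98 in these 2 mice, 10.4 in knockout 1 and 12.2 to 13.2 in the other 5. Of the measured markers, 9 of 21 skeletal muscle genes and 9 of 24 skin genes were detected on all 8 arrays, and whether the colon itself expresses them was not tested.

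The proliferation score was compared with those of the differentiated epithelium. The proliferation score minus the mean of the colonocyte, goblet, enteroendocrine and tuft cell scores was higher in knockout mice by 0.96 (exact permutation p = 0.0286, the smallest possible), while the mean of those 4 scores differed by -0.16 (exact permutation p = 0.0857). The proliferation score alone differed by 0.80 and already reached that smallest p, so the comparison adds no separate support. Its highest value, 1.21, was in knockout 4, which stood apart in all genes. Wnt target and stem cell genes had a score between -0.20 and 0.23 in all mice.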
